A study of Danio rerio with 2 samples.

How the data were processed

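Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in neuroblastoma cells of transgenic zebrafish. Per the labels' protocols, EGFP-positive tumour cells marked by a dbh:EGFP reporter were sorted by flow cytometry from mechanically dispersed tumours, 50000 cells were used per transposition, and libraries were sequenced on an Illumina HiSeq instrument. The dbh gene encodes dopamine beta-hydroxylase, an enzyme of noradrenaline synthesis. There was 1 library from tumours of MYCN transgenic fish and 1 library from tumours of MYC transgenic fish. The labels give no number of fish behind either library and no replicates.

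Reads were aligned with Bowtie2 2.2.1 to the zebrafish build danRer7 and peaks were called with MACS2 2.1.0, per the submitters' processing notes, which give no settings. Whether reads were shifted for the Tn5 insertion offset, whether duplicates were removed and whether a control library was used is not given in the sources used here. The authors deposited 1 peak list per library, with the chromosome, start, end and a score for each peak, and peaks were not pooled across libraries. The deposited score is a whole number per peak, and its smallest value is 13 in both lists. Such values fit 10 times the negative decimal logarithm of a q-value, as MACS2 writes it, with a limit near 0.05, but no header states this. Peak numbers ran without gaps from 1 to 68559 in the MYCN list and from 1 to 77836 in the MYC list. The smallest peak was 200 bp wide in both lists. Peaks lay on the 25 chromosomes and the mitochondrial genome, and none lay on unplaced scaffolds.

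Peak lists hold no read counts, so the sequencing depth behind each library is unknown from these values, and the number of peaks a caller finds grows with depth and with the ratio of signal to background. Each deposited score was therefore used only to rank or filter peaks within its own list, except in 1 setting that filtered both lists at the pooled median score and in the comparison of score spacing in the closing section. Scores of overlapping peaks are also printed side by side, but they need not be on the same scale. Intervals on shares are 95% Wilson intervals and cover counting error only. They do not cover differences between tumours, which 1 library per transgene cannot show, and no p-value for a difference between the transgenes was computed.

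A peak was called shared when it overlapped a peak of the other list by at least 1 bp, and list-only (MYCN-only or MYC-only) otherwise. Overlaps were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and the counts were checked against bedtools 2.31.1. Overlap by position alone was estimated from 100 circular shifts of the MYC list along each chromosome, up to the last peak of that chromosome. Peaks were divided into 10 equal classes by score within each list. On simulated lists of 20000 peaks with a known shared share of 75%, the overlap code returned 75%. For the regional comparison, list-only peaks were counted in windows of 1 Mb. The deviate of a window was its MYC-only count minus the count expected from the genome-wide share, divided by the binomial standard deviation. The spread of the deviates was set beside 1000 random reassignments of the sides over the same peaks. Per-chromosome shares were also given an interval from 1000 resamples of blocks of 5 Mb, since list-only peaks of the same kind lay together, and the resampling was repeated with 20 further random seeds. The largest step of the MYC-only share was sought on each chromosome at every 1 Mb boundary with at least 10 Mb on either side, and again in 1000 random orders of blocks of 5 Mb and of 10 Mb over the genome. This search was added after the values were seen. The longest series of consecutive peaks of a single list was set beside 1000 random orders of the same regions.

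The overlap comparisons, the alternatives for the shared shares and the ratios between lists, and the rule for the regions named below were fixed before the data were examined. The rule named the 10 highest-scoring peaks of each list without a peak of the other list within 1 kb, and the 5 highest-scoring and 5 widest shared peaks of each list. The chromosome, regional and score-spacing comparisons were added after the data were seen. The alternatives were reciprocal overlap of 50%, a distance of 500 bp, the longer list trimmed to the length of the shorter by score, peaks at or above the median score, removal of the mitochondrial peaks, and merging of peaks closer than 100 bp. A gene annotation and genome sequence of danRer7 were not used here, so peaks are given by position, starts counted from 1, and the promoter, gene list and motif comparisons planned at the outset were not run. Figures were drawn with matplotlib 3.10.9.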

Results

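ATAC-seq peak lists were compared between neuroblastoma cells sorted from MYCN transgenic zebrafish and from MYC transgenic zebrafish, to describe which parts of the genome were accessible in tumours driven by either member of the MYC family of transcription factors. MYCN is the member most often amplified in human neuroblastoma, and MYC is its close relative. Each transgene was represented by 1 library from 50000 sorted cells, with no replicate, so the differences below compare these libraries and cannot be set against the spread between tumours. The read depth of either library is unknown from the peak lists.

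More and slightly wider peaks were called in the MYC library than in the MYCN library, a difference that the unknown read depth may also affect. The MYC list held 77836 peaks covering 30.5 Mb, and the MYCN list held 68559 peaks covering 25.6 Mb. The MYC list therefore had 1.14 times as many peaks and covered 1.19 times as many bases. The covered bases made up 2.25% of the chromosome length spanned by the peaks in MYC and 1.89% in MYCN. The mean peak width was 392 bp in MYC and 374 bp in MYCN, and the median widths were 337 bp (quartiles 256 and 478) and 324 bp (quartiles 249 and 450). All 25 chromosomes carried more peaks in the MYC list. The median distance between neighbouring peaks was 9.19 kb in MYC and 11.1 kb in MYCN.

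Most accessible regions were called in both libraries. Of the MYCN peaks, 55934 overlapped a MYC peak, a share of 81.6% (95% Wilson interval 81.3 to 81.9). Of the MYC peaks, 55319 overlapped a MYCN peak, a share of 71.1% (70.8 to 71.4). When the MYC list was shifted along the chromosomes, the shared share averaged 4.31% of the MYCN peaks (range 4.14 to 4.49 over 100 shifts) and 3.79% of the MYC peaks (3.64 to 3.99). The observed shares were 18.9 and 18.7 times these values. The bases covered in both lists came to 20.0 Mb, which was 55.2% of the 36.2 Mb covered in either. Among 52912 peaks that overlapped exactly 1 peak of the other list, the scores had a Spearman correlation of 0.73, computed across peaks, which are not independent replicates. With reciprocal overlap of at least 50%, the shared shares were 73.4% for MYCN and 64.6% for MYC.

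The strongest accessible sites were almost all called in both libraries, and the sites called in a single list lay mainly at the weak end of that list. In the highest decile of each list by score, 99.5% of MYCN peaks (99.3 to 99.6) and 99.7% of MYC peaks (99.5 to 99.8) were shared. In the lowest decile, the shares were 48.9% (47.8 to 50.1) for MYCN and 33.6% (32.6 to 34.7) for MYC. The 12625 MYCN-only peaks had a median score of 55 and a median width of 247 bp, against 117 and 349 bp for the shared MYCN peaks. The 22517 MYC-only peaks had a median score of 57 and a median width of 252 bp, against 158 and 391 bp for the shared MYC peaks. Of the list-only peaks, 86.7% in MYCN and 86.5% in MYC had no peak of the other list within 1 kb. Only 35 MYCN-only peaks and 27 MYC-only peaks reached the highest decile of their list. List-only means only that no overlapping peak was called in the other list, where weaker signal cannot be seen. Weak peaks lie nearest the calling limit, so this gradient cannot be read as a difference between the transgenes.

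**Figure D1:**
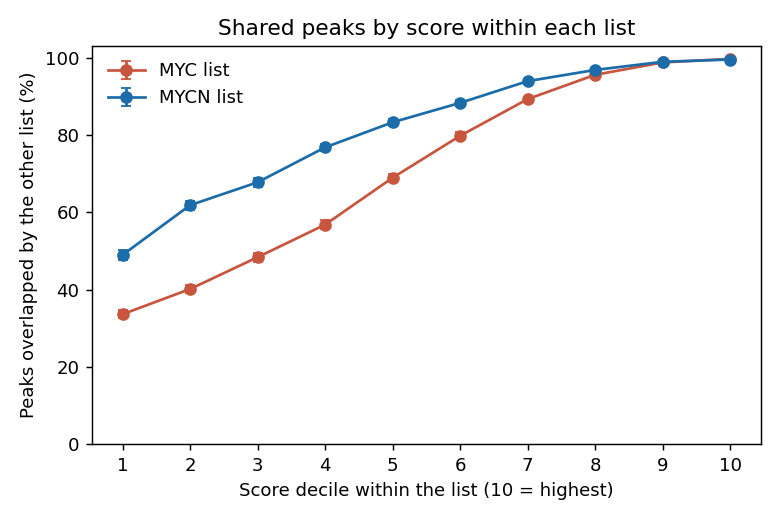
Share of peaks (vertical axis, percent) overlapped by at least 1 bp of a peak in the other list, for each score decile of the MYCN list (blue) and of the MYC list (red) ordered by peak score (horizontal axis, 10 is the highest). Bars are 95% Wilson intervals, and the shares climb from 48.9% to 99.5% in MYCN and from 33.6% to 99.7% in MYC.

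The leading sites of each list were shared and also ranked high in the other list, the lowest counterpart at rank 253 of 77836 MYC peaks. The highest-scoring peak of either list lay on chromosome 20 at 4645214 to 4645762 in MYCN, with a score of 2541, and at 4645207 to 4645753 in MYC, with a score of 1944. The site on chromosome 5 at 64236655 to 64237221 ranked 2 in MYCN with a score of 2312, and its MYC counterpart ranked 3 with a score of 1515. The site on chromosome 2 at 13838798 to 13839401 ranked 4 in MYCN with a score of 1472, and its MYC counterpart at 13838716 to 13839573 ranked 2 with a score of 1568. The other leading MYCN sites lay on chromosome 15 at 45149330 to 45150413, with a score of 1582 (MYC counterpart 1127, rank 10), and on chromosome 11 at 35982402 to 35983159, with a score of 1448 (MYC counterpart 875, rank 253). The other leading MYC sites lay on chromosome 10 at 16740309 to 16740850, with a score of 1272 (MYCN counterpart 1093, rank 9), and on chromosome 14 at 22220697 to 22221327, with a score of 1261 (MYCN counterpart 868, rank 36). All 20 highest-scoring peaks of each list were shared, and 9 of these sites belonged to the highest 20 of both lists.

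The widest shared regions included parts of the mitochondrial genome and several nuclear regions of more than 2 kb. The mitochondrial peak at 46 to 3577 was the widest of the MYCN list, at 3532 bp and a score of 318 (rank 6426 by score), and its MYC counterpart at 46 to 3588 had a score of 28 (rank 76313). The second mitochondrial region, at 13531 to 16543 in MYCN, had scores of 84 in MYCN and 85 in MYC. Its MYC peak, at 13218 to 16544, also overlapped a separate MYCN peak at 13237 to 13437 with a score of 24. The widest MYC peak lay on chromosome 5 at 1199089 to 1203907, spanned 4819 bp and overlapped 4 separate MYCN peaks, the widest of 1764 bp. The region on chromosome 4 at 43971087 to 43974036 was 2950 bp wide in MYC and overlapped 2 MYCN peaks that together spanned 43971087 to 43974054. The region on chromosome 11 at 18065024 to 18067965 was 2942 bp wide in MYC and overlapped 2 MYCN peaks that together spanned 18064608 to 18068613. The region on chromosome 7 at 64249112 to 64251273 was 2162 bp wide in MYCN and 2152 bp wide in MYC.

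Strong sites found in MYCN tumour cells without a MYC peak within 1 kb clustered in part on chromosome 6. Of the 10 highest-scoring sites of this kind, 3 lay within 7.25 kb of each other there, at 43363873 to 43364394 with a score of 812, at 43357148 to 43358129 with a score of 656, and at 43358762 to 43359084 with a score of 515. The nearest MYC peak was 30321 bp away or farther for each of them. A site on chromosome 22 at 7710038 to 7710653 had a score of 535, and the nearest MYC peak was 105245 bp away. The remaining 6 lay on chromosome 5 at 8181792 to 8182290 (score 502), on chromosome 19 at 33446786 to 33447361 (457), on chromosome 23 at 2175076 to 2175455 (406), on chromosome 7 at 6674907 to 6675249 (398), on chromosome 1 at 3453113 to 3453478 (379) and on chromosome 12 at 8121888 to 8122266 (379). The score of 812 was exceeded by 71 peaks of the MYCN list.

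Strong sites found in MYC tumour cells without a MYCN peak within 1 kb were spread over 9 chromosomes. The highest lay on chromosome 22 at 28947321 to 28947690, with a score of 904 that 179 peaks of the MYC list exceeded, and no other peak of either list lay within 50 kb of it. The next lay on chromosome 19 at 33576486 to 33577282 (score 687), on chromosome 21 at 3309794 to 3310371 (658), on chromosome 6 at 40529277 to 40529729 (622) and on chromosome 16 at 40014729 to 40015154 (583). Chromosome 4 held 2 of the 10, at 39985536 to 39985925 (526) and at 40341102 to 40341430 (453). The last 3 lay on chromosome 24 at 38934772 to 38935473 (470), on chromosome 9 at 2128682 to 2129066 (470) and on chromosome 3 at 9414126 to 9414769 (446).

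The excess of MYC-only sites differed along the genome more clearly than between chromosomes. Genome-wide, 64.1% of the list-only peaks were MYC-only (63.6 to 64.6), and per chromosome the share ran from 55.5% on chromosome 1 to 69.8% on chromosome 6. By counting error, the interval lay above the genome-wide share on 8 chromosomes and below it on 5. Independent peaks would put 1.25 of 25 outside such an interval by chance. When blocks of 5 Mb were resampled, the interval lay below on 2 chromosomes, chromosome 1 (51.0 to 59.9) and chromosome 12 (51.1 to 63.2). Each of 20 further draws gave the same, but they resampled the same blocks and add no evidence. With 8 to 16 blocks per chromosome, these intervals may be too narrow, and the number expected outside by chance is not known for them. Chromosome 6 was at the edge, since its lower limit of 64.08 barely exceeded the genome-wide 64.07 and its interval excluded that share in only 1 of 20 further draws, as did that of chromosome 9.

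**Figure D2:**
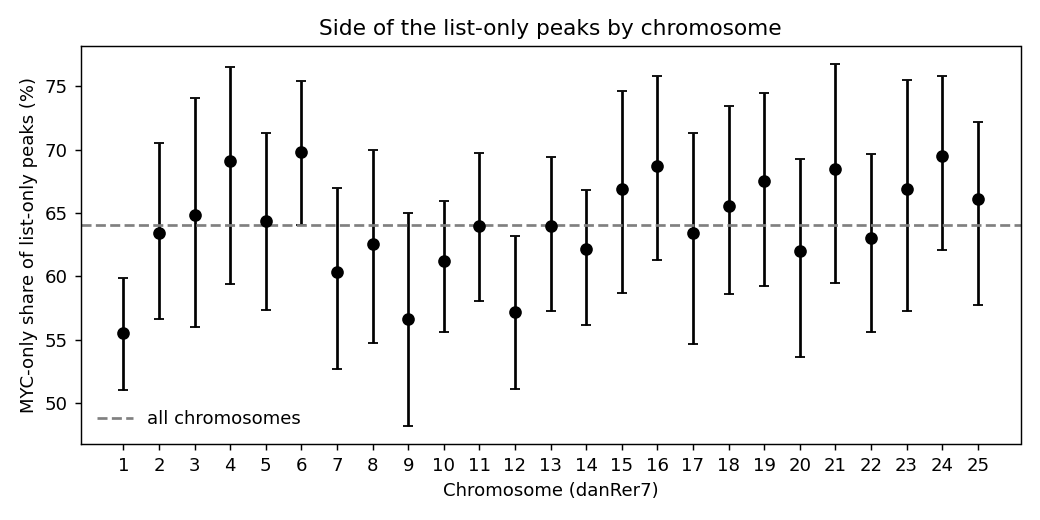
MYC-only share of all list-only peaks (vertical axis, percent, not starting at 0) on each of the 25 chromosomes (horizontal axis). Points are the observed shares, bars are 95% intervals from resampling 5 Mb blocks, and the dashed line is the genome-wide share of 64.1%, which the bars of chromosomes 1 and 12 exclude and the bar of chromosome 6 nearly touches.

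Within 1 Mb windows, list-only peaks of the same kind lay together. The deviates of the MYC-only share over 1369 windows had a standard deviation of 1.84, against 1.00 on average and at most 1.06 in 1000 random reassignments of the sides. The correlation of deviates was 0.51 between neighbouring windows, 0.26 at 5 Mb and 0.10 at 10 Mb, computed across windows, which are not replicates. Windows were ranked by deviate, which grows with the number of peaks, so windows with fewer peaks can have a more one-sided share. The largest deviates towards MYCN lay on chromosome 7 at 46 to 47 Mb, with 30 MYCN-only and 6 MYC-only peaks, and on chromosome 16 at 20 to 21 Mb, with 24 and 4. The largest deviates towards MYC lay on chromosome 20 at 30 to 31 Mb, with 38 MYC-only and 2 MYCN-only peaks, and on chromosome 4 at 11 to 12 Mb, with 37 and 2.

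The MYC-only share differed between the 2 sides of a cut by more than 20 points on more chromosomes than in nearly all random orders of blocks, while the largest difference, on chromosome 4, was within the random range. With each chromosome cut at the 1 Mb boundary, at least 10 Mb from either end, that gave the largest difference, the shares differed by 28.1 points on chromosome 4, 27.4 on chromosome 3 (76.0% before 38 Mb and 48.6% after) and 26.9 on chromosome 21 (77.0% before 28 Mb and 50.1% after), and by more than 20 points on 12 chromosomes. With the same search after intact blocks were put in random order over the genome, at most 8 chromosomes exceeded 20 points in 1000 orders of 5 Mb blocks and at most 12 in 1000 orders of 10 Mb blocks (medians 3 and 5). The largest difference had a median of 24.2 points with 5 Mb blocks and 27.4 with 10 Mb blocks, and it reached 28.1 in 120 and 399 of the orders. The long arm of chromosome 4 is known to be heterochromatic and poor in unique genes. In the first 22 Mb of the whole chromosome there were 80.8 MYC peaks and 55.0 MYCN peaks per Mb, and 83.0% of 873 list-only peaks were MYC-only (80.4 to 85.4). From 22 Mb to the end there were 31.8 MYC peaks and 29.7 MYCN peaks per Mb, and 54.9% of 863 list-only peaks were MYC-only (51.6 to 58.2). In steps of 5 Mb, the MYC-only share was 78.6% to 87.2% in the first 20 Mb, 71.1% in the step that holds the limit and 45.5% to 68.1% in the 8 steps after 25 Mb.

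**Figure D3:**
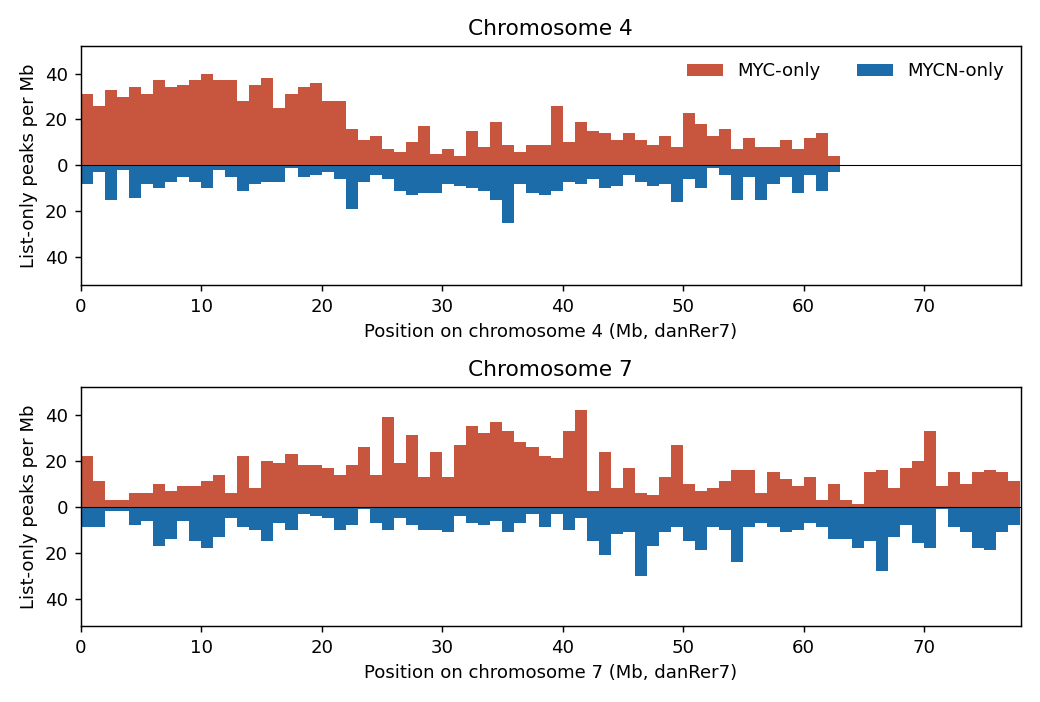
List-only peaks per 1 Mb window (vertical axis) along chromosomes 4 and 7 (horizontal axis, Mb, danRer7), with MYC-only peaks drawn upward in red and MYCN-only peaks downward in blue. On chromosome 4 the MYC-only peaks make up 83.0% of list-only peaks in the first 22 Mb and 54.9% after it, and on chromosome 7 the window at 46 to 47 Mb holds 30 MYCN-only and 6 MYC-only peaks.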

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

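The MYC over MYCN ratios of peaks and covered bases stayed at 1.13 to 1.14 and 1.19 without mitochondrial peaks and with peaks merged. These settings could hardly move them, since 3 MYCN and 2 MYC peaks were mitochondrial and merging left 67806 MYCN and 76945 MYC peaks. At or above the pooled median score the ratios were 1.26 and 1.32, but score steps were wider in MYC (mean 10.9 against 9.67 units), so 1 cut may not match both lists. Trimming MYC to an equal number of peaks left 1.099 times the bases. It removed the lowest-scoring MYC peaks, which were narrow (median width 214 bp in the lowest decile, 560 bp in the highest). A larger share of MYCN than of MYC peaks was shared under all 6 alternatives. The shared counts were nearly equal (55934 and 55319 in the main setting), so list length fixes this order where lengths differ. With 50% reciprocal overlap, 73.4% of MYCN and 64.6% of MYC peaks were shared, and 60.1% of list-only peaks were MYC-only. Allowing a distance under 500 bp gave 83.4% and 73.9%. Trimming the MYC list to the length of the MYCN list gave 77.1% and 76.0%, and the share of list-only peaks that were MYC-only is then held near equality by the equal lengths (51.2%), so it does not bear on the excess. With both lists cut at their own median score, 81.6% of MYCN and 70.2% of MYC peaks were shared, and 65.3% of list-only peaks were MYC-only. A peak whose counterpart fell below the other cut counted as list-only in this setting. Against the uncut other list, only 1562 of these 34355 MYCN peaks and 3121 of these 39793 MYC peaks were list-only. Removing mitochondrial peaks and merging peaks within 100 bp, which changed few peaks, moved no share beyond its interval. The spread of the window deviates was 1.54 in 500 kb windows, 2.25 in 2 Mb windows, and 1.83 to 1.87 with the trimmed list, without chromosome 4 and with peaks over 1 kb from the other list, each above its random reassignments. The alternatives for the list-only share and the windows were chosen after seeing the data. The other settings fixed for promoters, gene lists and motifs were not run, since an annotation and sequence of danRer7 were not used here. No replicate could be left out, and no paired analysis was possible because each transgene had 1 library. The unknown read depth limits every count of peaks.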

Other observations

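All tests in this part were chosen after the values were seen. Beyond the sites named above, stretches of consecutive accessible sites were called in a single list. The longest uninterrupted series in MYC was 16 consecutive peaks on chromosome 5 at 10481229 to 10717005, over 236 kb, where the MYCN list had no peak. In 1000 random orders of the same regions, the longest MYC series had a median of 8 peaks and at most 12. Random orders also remove the regional clustering of list-only peaks described above, so a longer series shows nothing beyond that clustering. Series of 12, 11, 10 and 10 MYC peaks without a MYCN peak lay on chromosome 7 at 18008814 to 18725810, chromosome 1 at 29894405 to 29984536, chromosome 17 at 11581889 to 11725881 and chromosome 20 at 52925709 to 53062706, none of them longer than the longest random series. In MYCN the longest series without a MYC peak had 11 peaks on chromosome 25 at 25966860 to 26030277, against a median of 5 and at most 9 in the random orders. Series of 8, 7, 7 and 7 MYCN peaks lay on chromosome 17 at 36743366 to 36883850, chromosome 7 at 44648242 to 44755313, chromosome 3 at 44985398 to 45156830 and chromosome 1 at 56004928 to 56175816, none of them longer than the longest random series. The highest score was 133 in the chromosome 5 series, 59 in the chromosome 25 series and 251 in the chromosome 17 series of MYCN. These series belong to 1 library each.

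The densest accessible regions held many peaks in both lists. In windows of 100 kb, the highest combined counts lay on chromosome 17 at 46600001 to 46700000, with 24 MYCN and 23 MYC peaks, of which 4 and 3 were list-only, and on chromosome 8 at 45700001 to 45800000, with 26 and 21, of which 8 and 2 were list-only. On chromosome 10 at 16700001 to 16800000 there were 23 MYCN and 22 MYC peaks, of which 3 and 0 were list-only. The next windows lay on chromosome 23 at 23100001 to 23200000, with 20 and 22 peaks, and on chromosome 3 at 24400001 to 24500000, with 19 and 22, and in each 3 MYCN and 6 MYC peaks were list-only. On chromosome 19, a strong MYCN-only site at 33446786 and a strong MYC-only site at 33576486 lay in the same region. No further MYCN peak lay within 50 kb of the first, and no MYCN peak lay within 50 kb of the second.

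The first pattern weighed was the larger number of MYC peaks. More reads kept in the MYC library could give it. The scores crowd at regular steps (26.4% of MYCN and 29.4% of MYC peaks lie on them between scores of 28 and 170), and if each step is 1 read of a Poisson score over a constant background, the wider MYC steps (mean 10.9 score units against 9.67 in MYCN, at scores of 35 to 150) correspond to a background 1.48 to 1.59 times higher in MYCN, where a simulated ratio of 1.5 was returned as 1.40 to 1.53. That cannot decide whether more reads were kept in MYC, since the backgrounds that fit the steps overlap (1.44 to 2.12 reads in MYCN and 1.02 to 1.62 in MYC with no further correction). The simulation assumed the same constant background, and the scoring formula is inferred from the values, so read depth stays open. A different calling threshold in terms of reads, a better ratio of signal to background in the MYC library and a difference between MYC and MYCN tumours also stay open and were not tested.

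The second pattern was that list-only peaks changed side by megabase region. Scatter of independent peaks is excluded by the spread of 1.84, above the highest value of 1.06 in 1000 reassignments, and gain or loss of whole chromosomes does not account for it, since the spread was 1.80 after each chromosome was given its own share, against at most 1.06. Peak density of the region, taken from the shared peaks, accounts for a small part: the MYC-only share was 53.1% in the quintile of windows with the fewest shared peaks and 70.1% in the quintile with the most, but the spread within quintiles was still 1.73, against at most 1.06. The pattern was not confined to weak peaks at the calling threshold, since the 1562 MYCN-only and 3121 MYC-only peaks at or above the median score of their whole list had a spread of 1.28, against at most 1.04. That spread cannot be set beside 1.84, since it rests on fewer peaks per window. Deviates of these stronger peaks and of the weaker list-only peaks had a correlation of 0.53 over 1285 windows, against at most 0.09 in the reassignments. Regional differences in calling sensitivity, copy-number changes of parts of chromosomes, base composition and a difference in chromatin domains between MYC and MYCN tumours or between individual fish stay open and untested, and the steps along the chromosomes may belong to any of them.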
